A study of Mus musculus with 4 samples.

How the data were processed

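Total RNA of sorted liver macrophages from Lyz2-Cre YFP reporter mice was sequenced in 4 libraries, 2 of YFP+ and 2 of YFP− cells. Groups were taken from the genotype label of each sample. Replicate numbers follow the order of deposit and were not used to pair libraries in the main model. Library titles begin with M or FM in each group, and these starts were used only as a secondary comparison and as a block. The sorting gate beyond YFP, the library kit and its strandedness are not given in the sources used here.

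Each library has its own gene table. Per the file headers the authors deposited 3 measures per gene: mean read coverage, FPKM (fragments per kilobase of gene per 1000000 mapped fragments) and TPM (the same scaled to a fixed sum). HISAT, without a version, and the builds GRCm38 and mm10 are named in the submitters' processing notes; the program that made the abundance tables is not given in the sources used here. TPM sums to 1000000 in every deposited table, so a gene's value depends on what else the library holds. Coverage divided by FPKM was the same within 1% for 83.1% to 85.3% of genes with coverage over 5, and this ratio served as the measure of depth. Read counts could not be recovered, since coverage times length gave a whole number of bases for only 56.2% to 65.5% of single-exon genes. No count test or counting interval was therefore used, and depth in reads is unknown. An exact 0 in such a table can be a failed estimate, so genes are said to be listed at 0.

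Rows of the same gene name were summed, which concerned 166 of 23337 names. Genes with at least 1 TPM in at least 2 libraries were kept, which left 12251. The values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend), Benjamini-Hochberg adjustment and a threshold of 0.05. The main model holds the YFP group alone, and the title start model holds the YFP group as a covariate. Error bars on fold changes are the moderated standard errors of limma.

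Gene lists were tested with camera at an inter-gene correlation of 0.01, two-sided, over lists with at least 3 tested members, with adjustment over lists. Of 573 entries in 36 lists fixed before the data were examined, 551 had a name in the files, 11 through an older symbol. The reporter loci list and the mitochondrially encoded list had too few tested members. Another 6 lists, of brain cell types, were added after seeing the data and were adjusted among themselves. Genes sharing reads with near-identical copies (H2-Q, Hbb, Hba, Mup and C4 families) are uncertain.

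Named genes follow a rule fixed before the data were examined. It takes the reporter loci, the 12 genes of largest log2 fold change in each direction that passed, moved the same way in both title starts and had a mean of at least 5 TPM in the higher group, and up to 4 members per list. Predicted genes are skipped, and some genes that the rule takes are not reported here. For the title starts it takes 5 genes per direction and all sex-linked transcripts.

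The gene test was tested on data simulated for the YFP comparison over 12251 genes. It called 3.0% of genes with a simulated log2 change of 2, 50.7% with 4 and 92.4% with 6. Of 101 calls, 4 were of unchanged genes. Noise was drawn independently per gene from the variances of the fit, without the shift of all genes seen in the data (median -1.73). Changed genes were drawn only from those of higher mean level. Simulated log2 values could also fall below 0, which log2(TPM + 1) cannot. The rates above thus hold for such genes under the test's own assumptions. They do not give its error rate in the data, or its rate of calling large falls there. The list test, on simulated lists of genes drawn independently, called the shifted list and 0 of the other lists. Correlations estimated in the tested lists reached 0.73 for ribosomal proteins and 0.79 for interferon-stimulated genes. This simulation therefore cannot show how often lists of correlated genes are called falsely.

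Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 TPM, quantile normalization, median-ratio scaling, the title start as a block, each library left out, a 2-fold minimum, an estimated correlation and fry. FPKM in place of TPM, cyclic loess, genes on a single row, quantile normalization with the block, and rescaling in the title start comparison and of the gene lists were chosen after seeing the data. Same-start libraries did not deviate together from their group means (correlation across genes -0.01). Transcript length and GC content came from GENCODE M21 (GRCm38). Other steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.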

Results

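RNA was sequenced from liver macrophages (Kupffer cells, the resident macrophages of the liver) sorted from reporter mice aged 6 to 8 weeks, of both sexes. In these mice Cre recombinase, made from the lysozyme gene Lyz2, switches on yellow fluorescent protein (YFP) at the Rosa locus, so a YFP+ cell or one of its precursors has expressed Cre. The 4 libraries comprised 2 from YFP+ and 2 from YFP− cells. One library of each group has a title beginning with M and the other a title beginning with FM; the labels do not say what these starts stand for. The deposited files hold 23337 gene names per library, with no read counts, so depth is known only from read coverage. At 1 FPKM, mean coverage was 4.81 in the YFP+ M, 9.19 in the YFP− M, 2.60 in the YFP+ FM and 2.59 in the YFP− FM library. At least 1 TPM was reached by 10302, 12434, 7386 and 12829 genes in the same order. The 100 most abundant genes took 54.0%, 40.9%, 66.1% and 29.7% of all TPM. Values below are mean TPM ± SD over n = 2 libraries per group, and fold changes are YFP+ minus YFP− on the log2(TPM + 1) scale, which understates the change of low genes.

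The main comparison asked how the transcriptomes of YFP+ and YFP− liver macrophages differ. Genes lowest in YFP+ libraries were led by Tmem119, a transmembrane protein used as a microglia marker, at 47.9 ± 63.6 against 1889 ± 865 TPM (log2 fold change -6.54, SE 0.89, adjusted p = 8.50e-10, chromosome 5, 113793729 to 113800352 in GRCm38). Olfml3, a secreted olfactomedin-domain protein, stood at 75.4 ± 98.9 against 2845 ± 165 TPM (-6.53, adjusted p = 7.05e-11), and Fcrls, an Fc receptor-like protein of microglia, at 80.7 ± 105 against 3082 ± 37.8 TPM (-6.53, adjusted p = 7.05e-11). Cx3cr1, the fractalkine receptor, was 65.5-fold lower in YFP+ libraries and Mbp, myelin basic protein, 73.4-fold lower on that scale. The other genes of this set were Siglech (-6.04), the fructose transporter Slc2a5 (-5.95), the adhesion receptor Gpr56 (-5.86), the ribonuclease Rnase4 (-5.76), the synaptic vesicle gene Syngr1 (-5.75), the G protein-coupled receptor Gpr34 (-5.74) and the protease inhibitor Serpine2 (-5.70), given as log2 fold changes. All 12 kept their call under quantile normalization and median-ratio scaling, while under cyclic loess Tmem119, Olfml3, Fcrls, Siglech, Cx3cr1, Syngr1 and Gpr34 no longer passed.

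Genes highest in YFP+ libraries were led by Apoc1, an apolipoprotein, at 7098 ± 1608 against 524 ± 456 TPM (log2 fold change 4.08, SE 0.69, adjusted p = 3.50e-06, chromosome 7, 19689481 to 19692658). Marco, a scavenger receptor of Kupffer cells, stood at 4563 ± 1807 against 453 ± 462 TPM (3.79, adjusted p = 6.12e-05, chromosome 1, 120474538 to 120505084). Cfp, which encodes the complement factor properdin, reached 5558 ± 998 against 660.2 ± 574 TPM (3.40, adjusted p = 0.000146), and Fcna, the lectin ficolin A, 7584 ± 944 against 980.0 ± 176 TPM (2.96, adjusted p = 0.000269). The neutrophil-attracting chemokines Cxcl2 and Cxcl1 had log2 fold changes of 3.07, adjusted p = 0.000984, and 2.84, adjusted p = 0.00898. Also in this set were the kinase gene Dmpk (2.95), the proteoglycan Sdc3 (2.92), the lipid droplet gene Hilpda (2.78), the proton pump subunit Atp6v0c (3.99) and the MHC class I genes H2-Q4 (2.94) and H2-Q2 (2.90). The H2-Q genes are near-identical copies, and Atp6v0c has processed copies in the genome, so how the authors' counting split their reads is uncertain. Atp6v0c differed widely between the YFP− libraries (303 ± 405 TPM). Under quantile normalization Apoc1, Marco, Cfp, Fcna and Atp6v0c no longer passed, with adjusted p of 0.0501, 0.0879, 0.102, 0.0658 and 0.181, and under median-ratio scaling Fcna did not (0.0527). Under loess Apoc1, Atp6v0c, Marco, Cfp, Cxcl2, Fcna, Sdc3 and Hilpda did not pass, and with the title start as a block Dmpk, H2-Q4, H2-Q2 and Cxcl1 did not.

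**Figure D1:**
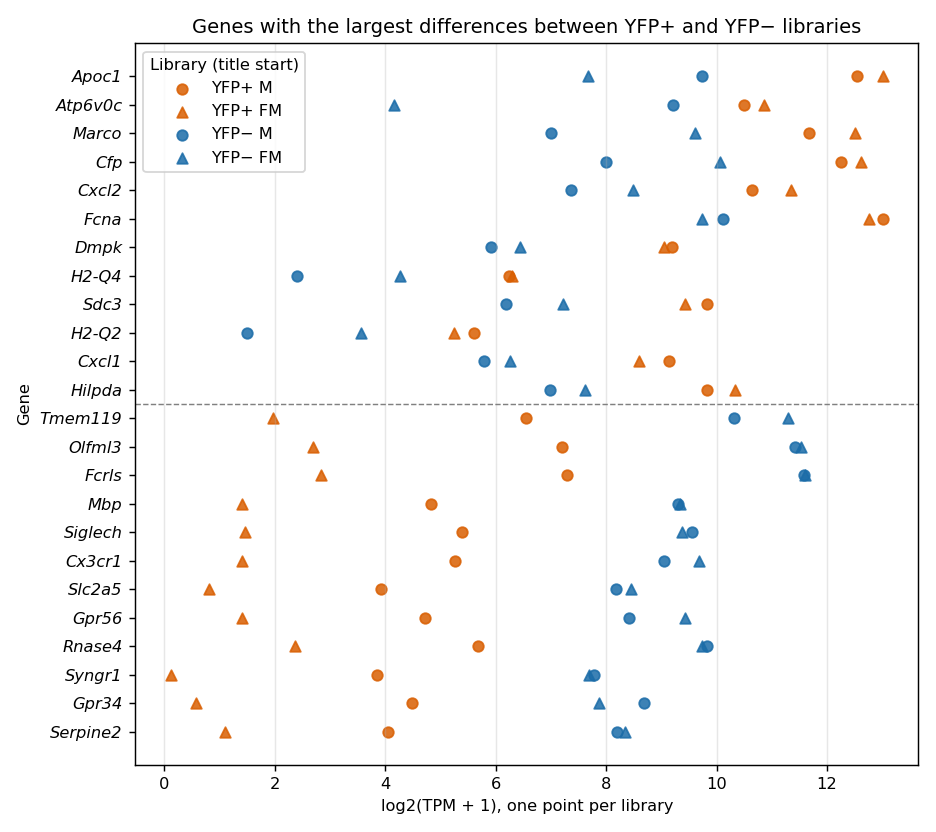
Expression of the 12 genes with the largest increase and the 12 with the largest decrease in YFP+ libraries, as log2(TPM + 1) on the horizontal axis, with a point per library (orange YFP+, blue YFP−, circles title start M, triangles FM). For the lower 12 genes both YFP+ points lie left of both YFP− points, and the YFP+ FM point lies left of the YFP+ M point; Fcrls stood at 155 TPM in YFP+ M and 6.15 in YFP+ FM, against 3055 and 3109 in the YFP− libraries.

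In all, limma-trend with Benjamini-Hochberg adjustment called 4898 of 12251 tested genes, 64 higher and 4834 lower in YFP+ libraries. Counts of list members that rose or fell, given below, are to be read against these shares of all genes. The median change of all tested genes was -1.73, with -1.01 between the M and -2.48 between the FM libraries, so a typical gene lay far below 0. When libraries were rescaled to a common distribution the median moved to -0.03 and quantile normalization called 148 higher and 205 lower, median-ratio scaling 688 and 724, and cyclic loess, chosen after seeing the data, 65 and 40. Calls in the deposited values and under each of these 3 scalings were 9 higher and 35 lower. Counts also moved with single libraries: without the YFP+ M library 8322 genes were called, without YFP+ FM 983, without YFP− M 97 and without YFP− FM 65. With the title start as a block 1749 were called. The labels do not say that libraries came from separate animals, so the spread between the libraries may be technical. In the main fit limma gave the variance trend infinite weight (prior degrees of freedom). Each gene's p-value therefore rests on the trend over all genes, whatever the spread of its own libraries. Under quantile normalization and loess the prior degrees of freedom were 6.87 and 5.56, so variance handling changed there along with scaling. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333.

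**Figure D2:**
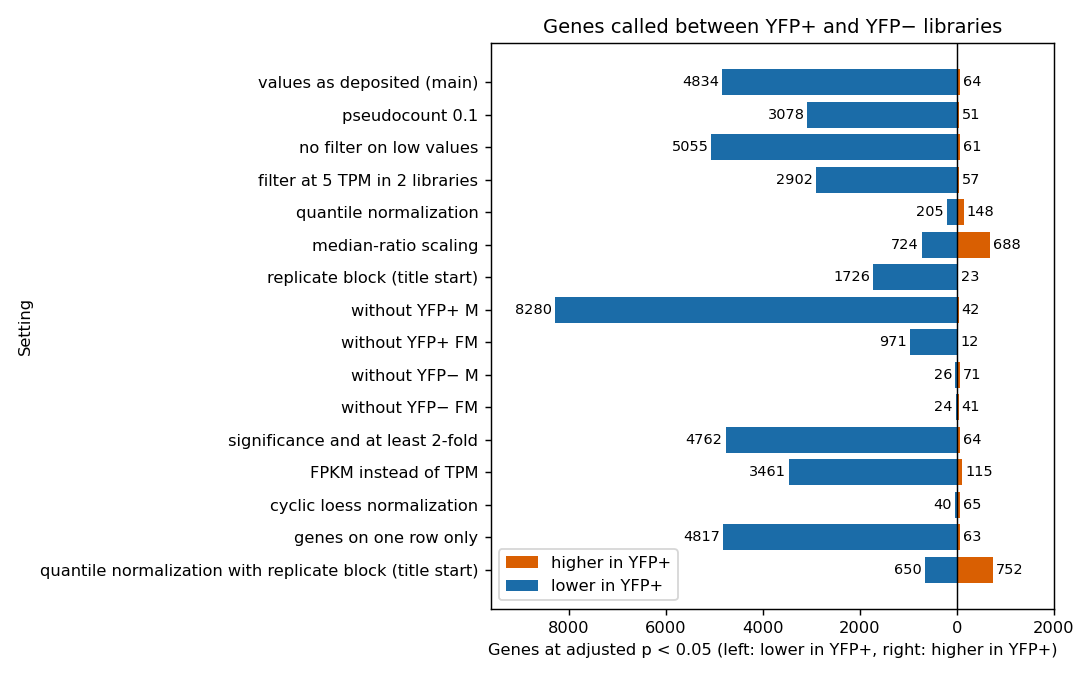
Number of genes at an adjusted p under 0.05 for each way of processing the values, with genes lower in YFP+ to the left of 0 and genes higher in YFP+ to the right. The deposited values give 4834 lower and 64 higher genes, while quantile normalization gives 205 and 148.

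Transcripts of the reporter loci did not pass on the deposited values. Lyz2, whose locus drives Cre (chromosome 10, 117277541 to 117282272), stood at 96.7 ± 65.4 against 42.3 ± 22.4 TPM (log2 fold change 1.10, SE 1.0, adjusted p = 0.344). Its difference was 2.39 between the M and -0.20 between the FM libraries, and under median-ratio scaling it was called (3.34, adjusted p = 0.0047). Its neighbour and paralog Lyz1 stood at 5.02 ± 1.62 against 26.4 ± 12.2 TPM (-2.14, adjusted p = 0.111), and how reads of these similar genes were split is uncertain. Gt(ROSA)26Sor, the locus that carries the YFP cassette, was below the filter at 1.11 TPM in YFP+ M, 0.711 in YFP− M and 0.404 in YFP− FM, and was listed at 0 in YFP+ FM.

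Kupffer cell identity genes stood above the rest of the transcriptome in YFP+ libraries. Of 22 tested members 5 rose and 0 fell (5 and 0 adjusted over the list alone), and the list's median change was 0.66, or 2.39 above that of all genes (camera above other genes, adjusted p = 3.26e-22, and adjusted p = 0.434 with an estimated correlation). The list's call held under quantile normalization (adjusted p = 1.59e-06) and loess (1.80e-05), but none of the 5 genes passed under quantile normalization. The 1 member called there was Paqr9 (adjusted p = 0.0377, and 0.634 on the deposited values), which like the other newly called genes below was named after the values were seen. Besides Marco, the scavenger protein Cd5l was at 11522 ± 479 against 3040 ± 2049 TPM, the folate receptor Folr2 at 3124 ± 684 against 655 ± 329.6 TPM, and the transcription regulator Id3 at 3075 ± 1362 against 598 ± 76.3 TPM. Under quantile normalization their adjusted p was 0.305, 0.146 and 0.121. Among classical markers chosen after their values were seen, the lectin Clec4f was at 8289 ± 1876 against 2702 ± 2399 TPM (1.96, adjusted p = 0.00849, and 0.369 under quantile normalization), while Timd4 (1.01, adjusted p = 0.288) and Vsig4 (1.16, adjusted p = 0.159) did not pass. Of 15 pan-macrophage genes 3 rose and 2 fell (3 and 1 adjusted over the list alone) (camera above other genes, adjusted p = 3.69e-06, and adjusted p = 0.527 with an estimated correlation), and the direction of the list turned under quantile normalization and loess. The complement component genes C1qa, C1qb and C1qc had log2 fold changes of 1.48, 1.46 and 1.46, with the sign turned under loess, and the integrin Itgam fell (-3.72).

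Lists of other macrophage states held genes that fell and none that rose, without a list call. Since 64 of all 12251 tested genes rose and 4834 fell, these counts alone do not set the lists apart. Of 15 monocyte and monocyte-derived macrophage genes 0 rose and 6 fell (0 and 6 adjusted over the list alone) (camera adjusted p = 0.675). Among them were Fn1, fibronectin (-4.00), and Ccr2, the monocyte chemokine receptor (-3.60). Of 12 capsular and lipid-associated macrophage genes 0 rose and 7 fell (0 and 7 adjusted over the list alone) (camera adjusted p = 0.0828). These included the lipid receptor Trem2, at 41.9 ± 44.7 against 1095 ± 5.98 TPM, and the tetraspanins Cd9 (-4.64) and Cd63 (-4.16). Of 7 genes of the ESAM and CD206 high Kupffer cell subset 0 rose and 4 fell (0 and 4 adjusted over the list alone) (camera adjusted p = 0.816). Its adhesion molecule Esam was at 12.2 ± 10.2 against 238 ± 54.2 TPM and Lyve1 at 3.93 ± 2.88 against 55.8 ± 47.8 TPM. Under quantile normalization 1 monocyte, 4 capsular and 1 ESAM subset genes were called lower, and Fn1 (adjusted p = 0.0542), Ccr2 (0.147) and Lyve1 (0.237) did not pass.

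Genes of liver sinusoidal endothelium that passed were lower in YFP+ libraries, although the list was not called on the deposited values. Of 20 liver sinusoidal endothelium genes 0 rose and 11 fell (0 and 13 adjusted over the list alone), and the list's camera adjusted p was 0.0828 on the deposited values, 0.00511 under quantile normalization and 0.00426 under loess, in the same direction. It was not called with an estimated correlation on the deposited values (adjusted p = 0.791), and 4 members were called lower under quantile normalization in place of 11. Its members furthest past the threshold were the tight junction gene Cldn5 (-5.28), Emcn (-4.43), the angiopoietin receptor Tek (-4.31) and Eng (-3.72), which vascular endothelium of many organs expresses. Of 9 stellate cell and fibroblast genes 0 rose and 7 fell (0 and 8 adjusted over the list alone) (camera below other genes, adjusted p = 0.0377, and adjusted p = 0.740 with an estimated correlation). The smooth muscle actin Acta2 was at 1.87 ± 1.85 against 64.4 ± 12.9 TPM and the pericyte gene Rgs5 at 0.235 ± 0.333 against 9.08 ± 3.01 TPM. The stellate call ended without YFP+ M (adjusted p = 0.378), YFP− M (0.885) or YFP− FM (0.998). Of 19 hepatocyte genes 0 rose and 5 fell (0 and 3 adjusted over the list alone) (camera adjusted p = 0.0828). Among those that fell was Ttr, the thyroxine carrier made by hepatocytes and choroid plexus, at 53.7 ± 2.58 against 942 ± 158 TPM. Of 3 cholangiocyte genes 0 rose and 1 fell (0 and 1 adjusted over the list alone) (camera adjusted p = 0.979). Under quantile normalization 1 stellate, 1 hepatocyte and 0 cholangiocyte genes were called lower, and Emcn (adjusted p = 0.0974), Eng (0.0638) and Rgs5 (0.0750) did not pass.

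None of the tested genes in the lists of other blood cells rose. Of all 12251 tested genes 64 rose and 4834 fell, so a lack of higher genes does not set these lists apart. Among 14 neutrophil genes 0 rose and 1 fell (0 and 1 adjusted over the list alone) (camera above other genes, adjusted p = 0.0377, and adjusted p = 0.740 with an estimated correlation). The list's direction turned under loess, without YFP+ FM (adjusted p = 0.978) and without YFP− M (0.490). The receptor Csf3r fell (-2.99), and the abundant calprotectin subunit S100a9 was at 2823 ± 2901 against 1205 ± 552 TPM (0.77, adjusted p = 0.341). Among 14 conventional dendritic cell genes 0 rose and 9 fell (0 and 9 adjusted over the list alone) (camera adjusted p = 0.644), including Zbtb46 (-2.55) and Itgae (-3.37). Among 9 plasmacytoid genes 0 rose and 5 fell (0 and 6 adjusted over the list alone) (camera adjusted p = 0.422), including Siglech. For 14 T and NK cell genes 0 rose and 9 fell (0 and 11 adjusted over the list alone) (camera adjusted p = 0.447). The granzyme Gzma was at 45.6 ± 10.4 against 292 ± 214 TPM and Cd3e at 6.56 ± 5.65 against 43.6 ± 1.51 TPM. For 8 B and plasma cell genes 0 rose and 3 fell (0 and 3 adjusted over the list alone) (camera adjusted p = 0.816), with Ms4a1 (-3.11). For 6 platelet and megakaryocyte genes 0 rose and 4 fell (0 and 5 adjusted over the list alone) (camera below other genes, adjusted p = 0.0373, and adjusted p = 0.688 with an estimated correlation), with Gp9 (-3.55). For 4 basophil and mast cell genes 0 rose and 2 fell (0 and 2 adjusted over the list alone) (camera adjusted p = 0.189). Of 5 erythroid genes 0 rose and 0 fell (0 and 0 adjusted over the list alone). This list was called (camera above other genes, adjusted p = 0.0139, and adjusted p = 0.593 with an estimated correlation), with the direction turned under loess and no call without YFP− FM (adjusted p = 0.468). The platelet call ended without YFP+ M (adjusted p = 0.399). Under quantile normalization Siglech was the 1 gene of these blood cell lists that was called.

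The MHC class I, MHC class II, inflammatory and interferon-stimulated lists lay above other genes on the deposited values, while the Toll-like receptor and alternative activation lists were not called. Of 13 MHC class II genes 3 rose and 1 fell (2 and 1 adjusted over the list alone) (camera above other genes, adjusted p = 2.37e-07, and adjusted p = 0.434 with an estimated correlation). H2-Aa (2.18), the invariant chain Cd74 (1.61, turned under loess) and H2-Ab1 (1.5) were higher, and H2-Ob (-3.11) lower. Of 11 MHC class I genes 2 rose and 0 fell (2 and 0 adjusted over the list alone) (camera above other genes, adjusted p = 4.61e-09, and adjusted p = 0.434 with an estimated correlation). H2-D1 was at 12415 ± 14.2 against 3663 ± 1345 TPM and H2-K1 at 9936 ± 367 against 3455 ± 1072 TPM. B2m was at 13141 ± 1433 against 6433 ± 4801 TPM (1.26, adjusted p = 0.0573, turned under loess). Of 23 inflammatory cytokine and chemokine genes 3 rose and 4 fell (3 and 1 adjusted over the list alone) (camera above other genes, adjusted p = 1.00e-09, and adjusted p = 0.434 with an estimated correlation). That call held under quantile normalization (adjusted p = 0.00511) and loess (0.0233). The calls of MHC class II (adjusted p = 0.250 and 0.432), MHC class I (0.0725 and 0.278) and interferon-stimulated genes (0.0725 and 0.0893) ended under the same settings, and the last also without YFP− M (0.587). Under quantile normalization Cxcl1 and Cxcl2 kept their calls, Il1b (adjusted p = 0.279) and Irf7 (0.123) did not, and Il10 (0.0342) and Isg15 (0.0377) were newly called higher. No other gene of these antigen presentation and inflammation lists was called there. Il1b, interleukin 1 beta, rose together with Cxcl1 and Cxcl2, at 3323 ± 506 against 750.2 ± 740.0 TPM, and Nos2, which makes nitric oxide, fell at 0.103 ± 0.0365 against 3.66 ± 0.185 TPM. Of 24 interferon-stimulated genes 1 rose and 1 fell (0 and 0 adjusted over the list alone) (camera above other genes, adjusted p = 0.000187, and adjusted p = 0.740 with an estimated correlation). The transcription factor Irf7 was higher (2.31), the GTPase Irgm1 lower (-2.96) and Cxcl10 did not pass (1.81, adjusted p = 0.0668). For 22 Toll-like receptor and NF-kB genes 2 rose and 7 fell (2 and 11 adjusted over the list alone) (camera adjusted p = 0.264), with the NF-kB inhibitor Nfkbia (2.10) higher and Tlr7 (-3.66) lower. For 12 alternative activation genes 0 rose and 2 fell (0 and 1 adjusted over the list alone) (camera adjusted p = 0.0907).

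Complement, scavenger, iron and cholesterol lists each held genes that rose and genes that fell, and the lysosome list held none that rose. Of 17 complement genes 5 rose and 4 fell (5 and 4 adjusted over the list alone) (camera above other genes, adjusted p = 9.44e-09, and adjusted p = 0.527 with an estimated correlation), with Cfp and the C1q genes among the higher ones. Of 21 scavenger and phagocytic receptor genes 2 rose and 5 fell (1 and 4 adjusted over the list alone) (camera above other genes, adjusted p = 3.69e-06, and adjusted p = 0.688 with an estimated correlation): Marco was higher, while Gas6 (-4.54) and Pros1 (-4.25), ligands that bridge dying cells to their receptors, were lower. Of 16 iron and heme genes 3 rose and 2 fell (3 and 2 adjusted over the list alone) (camera above other genes, adjusted p = 1.10e-07, and adjusted p = 0.527 with an estimated correlation), with biliverdin reductase Blvrb (2.58) and the ferritin chains Ftl1 (1.53) and Fth1 (1.49) higher, the ferritin signs turning under loess. Of 19 cholesterol and LXR target genes 2 rose and 7 fell (2 and 9 adjusted over the list alone) (camera above other genes, adjusted p = 0.00102, and adjusted p = 0.740 with an estimated correlation). Here the median lay -0.26 from that of all genes, opposite in sign to the test, with the apolipoproteins Apoe (17642 ± 4864 against 3631 ± 1111 TPM) and Apoc1 higher and the acyltransferase Lpcat3 (-2.84) lower. Of 24 lysosome genes 0 rose and 3 fell (0 and 1 adjusted over the list alone) (camera above other genes, adjusted p = 0.00637, and adjusted p = 0.740 with an estimated correlation), and this list's direction turned under quantile normalization and loess and without YFP− M (adjusted p = 0.490). Without YFP− FM its call ended (adjusted p = 0.158). Under quantile normalization no complement, scavenger, iron or cholesterol gene that rose kept its call, including Cfp (adjusted p = 0.102), Blvrb (0.104), Ftl1 (0.521), Fth1 (0.588) and Apoe (0.180). The complement receptor gene C5ar1 (0.0379) and the heme oxygenase Hmox1 (0.0311) were newly called higher, Gas6 and 1 lysosome gene kept their calls, and Pros1 (0.0517) did not. The protease Ctsd was at 4807 ± 909 against 10519 ± 40.3 TPM (-1.14, adjusted p = 0.0894).

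Most genes of the housekeeping lists did not pass, although camera placed these lists above other genes. Of 26 cytosolic ribosomal protein genes 0 rose and 0 fell (0 and 0 adjusted over the list alone) (camera above other genes, adjusted p = 7.82e-21, and adjusted p = 0.564 with an estimated correlation), and the direction turned under quantile normalization and loess. Of 24 oxidative phosphorylation genes 1 rose and 1 fell (0 and 0 adjusted over the list alone) (camera above other genes, adjusted p = 5.47e-06, and adjusted p = 0.688 with an estimated correlation). The cytochrome oxidase subunit Cox5a was higher (2.08). Of 16 glycolysis genes 0 rose and 2 fell (0 and 2 adjusted over the list alone) (camera above other genes, adjusted p = 0.0139, and adjusted p = 0.740 with an estimated correlation), with the direction turned under quantile normalization and loess. The glucose transporter Slc2a1 fell (-4.43), and Gapdh was at 2238 ± 199 against 1241 ± 32 TPM (0.85, adjusted p = 0.287). Of 24 proliferation genes 0 rose and 2 fell (0 and 1 adjusted over the list alone) (camera above other genes, adjusted p = 0.0377, and adjusted p = 0.821 with an estimated correlation). Of 23 dissociation and immediate-early genes 0 rose and 4 fell (0 and 0 adjusted over the list alone) (camera above other genes, adjusted p = 1.67e-06, and adjusted p = 0.688 with an estimated correlation), with the direction turned under loess. Jun was at 56.3 ± 18.2 against 353 ± 268 TPM and Hsp90aa1 at 61.2 ± 32 against 330.2 ± 14.6 TPM. Without YFP− M the glycolysis (adjusted p = 0.885), proliferation (0.885) and dissociation calls (0.104) ended. Without YFP− FM those of oxidative phosphorylation (0.529) and proliferation (0.0797) did. The proliferation call also ended without YFP+ M (0.154), and that of glycolysis without YFP+ FM (0.0634). Under quantile normalization Slc2a1 kept its call and no other gene of these housekeeping lists was called. Of the lists fixed beforehand and called on the deposited values, Kupffer cell identity and inflammatory genes were the ones still called under both quantile normalization and loess. Median-ratio scaling ended the neutrophil, stellate, platelet, erythroid and cholesterol calls. Removal of the filter ended 5 list calls, a pseudocount of 0.1 ended 2 and the filter at 5 TPM ended 1. For the MHC class II, inflammatory and complement lists the median change was above 0 and the mean below it (-0.20, -0.04 and -0.13). Fry, which tests a list's change against 0 and not against other genes, called 0 of the lists fixed beforehand, with 4 at an unadjusted p under 0.05. Camera with an estimated correlation called 0, with 3 at that level.

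Because microglia markers led the lower genes, 6 lists of brain cell types were added after these values were seen, so their counts are not independent evidence of direction. Of 32 microglia genes 0 rose and 31 fell (0 and 32 adjusted over the list alone), with a median change -3.36 from that of all genes (camera below other genes, adjusted p = 7.80e-31, and adjusted p = 0.278 with an estimated correlation). Of 22 genes of blood-brain barrier endothelium 0 rose and 22 fell (0 and 22 adjusted over the list alone) (median -2.68 from all genes, camera below other genes, adjusted p = 1.05e-13, and adjusted p = 0.278 with an estimated correlation). These include Ly6c1 (-4.94) and the thyroxine transporter Slco1c1, at 6.57 ± 7.95 against 209.7 ± 106 TPM. Of 12 astrocyte genes 0 rose and 9 fell (0 and 9 adjusted over the list alone) (camera below other genes, adjusted p = 0.00174, and adjusted p = 0.353 with an estimated correlation), with Mlc1 (-3.74). Of 10 choroid plexus genes 0 rose and 9 fell (0 and 9 adjusted over the list alone) (camera below other genes, adjusted p = 5.31e-06, and adjusted p = 0.278 with an estimated correlation), with Ttr and Enpp2, the enzyme autotaxin (-5.41). Of 6 oligodendrocyte genes 0 rose and 4 fell (0 and 4 adjusted over the list alone) (camera below other genes, adjusted p = 0.00174, and adjusted p = 0.278 with an estimated correlation), with Mbp, and of 4 neuron genes 0 rose and 2 fell (0 and 2 adjusted over the list alone) (camera adjusted p = 0.553). Under quantile normalization 27 microglia, 11 blood-brain barrier, 3 oligodendrocyte, 2 astrocyte and 2 choroid plexus genes were called lower, and the neuron gene Rbfox3 was newly called higher (adjusted p = 0.0311). All gene groups above were measured in libraries that also carried this difference, and a mix-up or mislabelling of samples was not excluded.

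**Figure D3:**
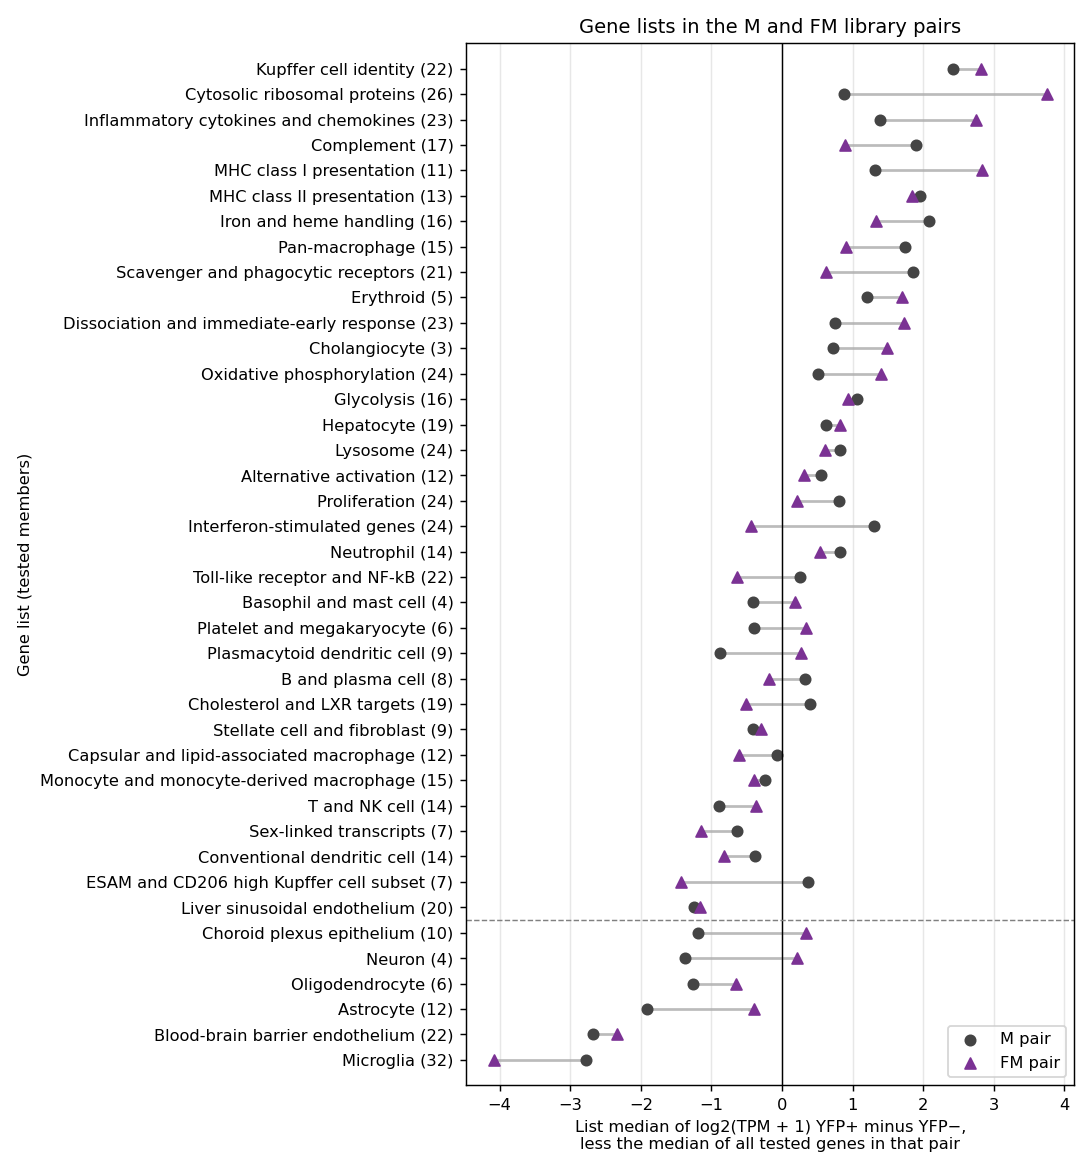
Median log2 difference of each gene list, YFP+ minus YFP− on the log2(TPM + 1) scale and less the median of all tested genes, between the M libraries (circles) and the FM libraries (triangles), with tested members in parentheses. Lists under the dashed line were added after seeing the data. Kupffer cell identity lies above 0 in both pairs, and microglia and blood-brain barrier endothelium lie below 0 in both, furthest of all lists.

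The title starts were compared with the YFP group as a covariate. Of 12251 genes, 6 passed, with 87 at an unadjusted p under 0.05. Hbb-b2, a beta globin, was higher in the FM libraries, and 5 were lower, Mup2, Mup15, Mup19, Gm7334 and 1700025K23Rik. The last pair, predicted genes, was named after the values were seen because the count was small. Mup genes encode major urinary proteins, pheromone carriers made by the liver. Mup15 was at 1.32 TPM in YFP+ M and 24.0 in YFP− M and was listed at 0 in both FM libraries (log2 fold change FM minus M -2.93, SE 0.69, adjusted p = 0.0393). Mup2 (-2.90) and Mup19 (-2.29) were likewise listed at 0 in both FM libraries, and Mup11 (-3.22, adjusted p = 0.0543) and Mup12 (-3.13, adjusted p = 0.0518) did not pass. The Mup genes are near-identical copies, so values of single members are uncertain. Among genes higher in FM libraries without passing were Orm2 (2.12), Gpr77 (2.08), Plg (2.09), Tarm1 (1.90) and Pira11 (1.80), each at adjusted p = 1.0. Hbb-b2 was at 2173 TPM in YFP+ M, 0.770 in YFP− M, 1121 in YFP+ FM and 2125 in YFP− FM, while its near-identical neighbour Hbb-b1 was at 19.2, 1793, 6.43 and 19.0 TPM. Their sum was 2192, 1794, 1128 and 2144 TPM. Without the YFP covariate limma called 0 genes, with 9 at an unadjusted p under 0.05, while quantile normalization called 119 and median-ratio scaling 110.

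Sex-linked transcripts were read out in each library because mice of both sexes were used. The Y-linked Eif2s3y was at 10.02 TPM in YFP+ M, 39.7 in YFP− M and 20.2 in YFP− FM and was listed at 0 in YFP+ FM. Ddx3y was at 2.68, 12.6 and 4.62 TPM, Kdm5d at 1.15, 4.06 and 4.04, and Uty at 0.428, 2.07 and 0.478 in the same libraries, again listed at 0 in YFP+ FM. Xist, the RNA that silences an X chromosome in females, was at 0.330, 0.196 and 3.33 TPM in these libraries and at 0.210 in YFP+ FM. Its antisense partner Tsix was at 1.61 TPM in YFP+ FM and 0.672 in YFP− FM and was listed at 0 in both M libraries, and without strand their reads cannot be told apart. None of the 7 tested sex-linked genes passed between title starts. Ddx3y (-1.58), Eif2s3y (-2.20), Kdm5d (-0.56), Ddx3x (-0.69), Eif2s3x (0.04), Kdm5c (0.28) and Kdm6a (0.32) had adjusted p = 1.0, although Ddx3y and Eif2s3y passed under quantile normalization and median-ratio scaling. By list, 7 sex-linked genes showed 0 rose and 6 fell (0 and 6 adjusted over the list alone) in YFP+ libraries (camera adjusted p = 0.302).

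Gene lists were also compared between title starts. Camera called 14 of 34 lists with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.879 and 0 had an unadjusted p under 0.05. Neutrophil genes lay highest in FM libraries (median 1.45 above that of all genes, adjusted p = 1.53e-14), followed by complement (0.86, 7.28e-07), hepatocyte (0.92, 0.000977), interferon-stimulated (0.61, 0.000977) and dissociation genes (0.53, 0.00113). Cholangiocyte, glycolysis, inflammatory, Toll-like receptor, monocyte and stellate lists were also higher, with adjusted p of 0.0123, 0.0182, 0.0260, 0.0317, 0.0333 and 0.0333. Plasmacytoid dendritic cell (adjusted p = 0.00426), B and plasma cell (0.0183) and oxidative phosphorylation genes (0.0226) were lower.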

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

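Values here were looked at for opposite signs in the M and FM library pairs, each pair holding a YFP+ and a YFP− library, on the log2(TPM + 1) scale. With a library per cell of the design the difference was not tested in any of these cases, and the check was chosen after the data were seen. Of 95 genes named in the text, 2 had opposite signs. This share says little about agreement, since the genes of largest change were chosen to move the same way in both title starts. Genes of the naming rule that are not reported here, such as Hba-a1 (-0.60 and 2.53), were not looked at. Over all tested genes 86.6% had the same direction in both pairs. Lyz2 was higher in YFP+ between the M libraries (2.39) and lower between the FM libraries (-0.20), a difference of -2.59. S100a9 went from -0.08 to 1.61, a difference of 1.69.

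Among 34 gene lists, the median change, measured from 0, had opposite signs in 9. The medians were above 0 between the M and below 0 between the FM libraries for pan-macrophage genes (FM minus M -2.29), erythroid genes (-0.98), MHC class II presentation (-1.57), interferon-stimulated genes (-3.21), scavenger receptors (-2.70), complement (-2.48), iron and heme handling (-2.21) and glycolysis (-1.59). Cytosolic ribosomal proteins went the other way, from -0.14 to 1.27, a difference of 1.41. The median of all genes itself differed between the pairs, at -1.01 and -2.48, and these differences were not tested either. Measured from that median, the same lists lay above it in both pairs, so their signs were no longer opposite. The exception was interferon-stimulated genes, which lay above it between the M libraries and below it between the FM libraries (-2.91 against -2.48).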

How the results depend on the processing

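FPKM, cyclic loess, genes on a single row, quantile normalization with the replicate block, and rescaling of the gene lists and of the title start comparison were chosen after seeing the data. The 4898 genes called for YFP+ against YFP− (64 higher, 4834 lower) became 3129 with a pseudocount of 0.1 (3078 lower), 2959 with a filter at 5 TPM (2902 lower), 353 with quantile normalization (148 higher, 205 lower), 1412 with median-ratio scaling (688 and 724) and 105 with loess (65 and 40). With the title start as a replicate block 1749 were called (23 and 1726), and with that block after quantile normalization 1402 (752 and 650). FPKM gave 115 higher genes among 3576 calls. Removal of the filter (5116), genes on a single row (4880) and a 2-fold minimum (4826) stayed within 1.5 times. Leaving out each library in turn gave 65 to 8322 calls, 12 to 71 higher and 24 to 8280 lower, with the lone library of a group assumed to vary like the others; the lowest counts came without a YFP− library, where fewer genes passed the filter. The labels do not say whether same-start libraries share animals. Their deviations from the group means had a correlation across genes of -0.01, which cannot show whether they are paired.

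Of the gene lists, 20 were called, and 0 with an estimated correlation, 0 with fry and 3 each under quantile normalization (with or without the replicate block) and loess; leaving out a library gave 14 to 19. List values are medians minus that of all genes, and directions are those of the test. Under quantile normalization, with and without the replicate block, the direction turned for ribosomal proteins (0.0166), glycolysis (-0.0461), lysosome (-0.32) and pan-macrophage genes (0.0745). Under loess it turned for the same lists (-0.27, -0.0628, -0.51 and -0.27), the dissociation list (0.13), erythroid (0.41) and neutrophil genes (0.20). Fry, which tests against 0 and not against other genes, gave the opposite direction for 15 lists with these medians: cholesterol -0.26, complement 2.06, dissociation 1.34, erythroid 1.44, glycolysis 0.88, inflammatory 2.19, interferon 0.35, iron 1.51, lysosome 0.70, MHC class II 1.89, neutrophil 0.33, oxidative phosphorylation 0.98, pan-macrophage 1.49, proliferation 0.58 and scavenger 1.48. Without YFP− M the direction turned for lysosome (0.81; 0.71 to 0.89 over left-out libraries) and neutrophil genes (-0.16), and without YFP+ FM for neutrophil genes (0.028; range -0.16 to 1.55).

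Of the named genes, loess turned the sign of B2m (-0.41), C1qa (-0.15), C1qb (-0.24), C1qc (-0.28), Cd74 (-0.25), Fth1 (-0.14), Ftl1 (-0.43) and Lyz1 (0.0013). Ctsd turned under median-ratio scaling (1.16) and S100a9 without YFP+ FM (-0.56; range -0.56 to 2.10). Loess ended the calls of Tmem119, Olfml3, Fcrls, Siglech, Cx3cr1, Syngr1 and Gpr34 among the genes of largest decrease and of Apoc1, Atp6v0c, Marco, Cfp, Cxcl2, Fcna, Sdc3 and Hilpda among those of largest increase, with no change of sign. Among the same genes the title start block ended those of Dmpk, H2-Q4, H2-Q2 and Cxcl1. Over all 95 named genes, loess ended 58 calls, quantile normalization 47, the title start block 34 and median-ratio scaling 32. Calls of named genes also ended when a library was left out, and these are not listed here. For the title starts, 6 genes became 40 without the filter, 119 with quantile normalization, 110 with median-ratio scaling and 0 without the YFP covariate; Eif2s3x turned with a pseudocount of 0.1 (-0.063), and 14 called lists became 0 with an estimated correlation. Leaving out a library could not be fitted there, since no residual degree of freedom remains. Alternatives that need read counts (other size factors, upper-quartile scaling, count models, a count filter) were not run because the values are not counts. The cause of these changes was not tested.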

Other observations

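The tests in this part were all chosen after the results were seen. Genes called in the deposited values and under quantile normalization, median-ratio scaling and cyclic loess numbered 9 higher and 35 lower in YFP+ libraries. The higher ones were Cxcl1, Dmpk, H2-Q2, H2-Q4, H2-Bl, Bcl2a1c, Scarna17, Mir1956 and Mir3100. With the title start as a block Cxcl1, Dmpk, H2-Q2 and H2-Q4 did not pass, and values of the near-identical H2-Q genes are uncertain. Scarna17, Mir1956 and Mir3100 are small RNA genes, and how well such tables measure them was not checked. The lower ones included Sall1, a transcription factor of microglia, the adenosine receptor gene Adora3, the TGF-beta receptor gene Tgfbr2 and Trem2. They also included Cldn5, Slc2a1, Slc22a8 and Spock2 of the brain vessel list, Mbp of the oligodendrocyte list and Enpp2 of the choroid plexus list. Others, such as Alpl, Arsb, Atp1b2, Capn3, Ldhb, Mlxipl, Ndrg2, Slc38a3 and Tgfa, are in none of the lists. Whether any list is over-represented among these genes was not tested.

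Summed Xist and Tsix values were 0.330 TPM in YFP+ M, 0.196 in YFP− M, 1.82 in YFP+ FM and 4.004 in YFP− FM.

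Microglia genes and brain vessel genes were both low in YFP+ libraries, while the labels name liver as the tissue and a sort on YFP, with no further gate. Liver sinusoidal endothelium as the origin of the vessel genes was examined with 6 genes restricted to that endothelium. Their median change, -0.78, lay 3.63 above that of the brain vessel list, more than either set's interquartile range. Genes of low level cannot fall far on the log2(TPM + 1) scale, and the levels of these 6 genes were not compared with those of the vessel genes. The gap therefore does not decide whether the vessel genes have this origin. The full sinusoidal list of 20 genes, some of which vessels of many organs express, lay closer to the brain vessel list, with medians of -2.89 and -4.41. A microglia-like state of the YFP− macrophages with no other cells is argued against for the vessel genes, whose median lay -2.68 from that of all genes; for the microglia genes (-3.36) it cannot be told apart from microglia RNA, since the group and the RNA source coincide. A candidate explanation that stays open is RNA of microglia and of brain vessel, glial and choroid plexus cells in the YFP− libraries. Tested were 32 genes from 4 brain lists other than microglia and vessel. Of them 46.9% lay below the median of all genes in both pairs, against 33.7% of all tested genes. But 9 of them averaged under 5 TPM in YFP− libraries, of which 0 met that criterion. With a limit of 5 TPM over all libraries, chosen after the first share was seen, the shares were 65.0% of 20 genes and 39.7%. For genes low in YFP+ libraries the YFP− values carry a mean over all libraries. That limit thus partly selects for the difference, and the higher share is no further evidence. A mix-up or mislabelling of samples that brought in such RNA was not tested and would change what every YFP+ against YFP− value means; both YFP− libraries (M and FM) also held Kupffer cell transcripts, with Cd5l at 1591 and 4489 TPM and Clec4f at 1006 and 4398 TPM.

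Abundant members of the microglia and vessel lists reached 3055 and 3109 TPM (Fcrls) and 1147 and 433 (Ly6c1) in YFP− M and FM. List medians in these libraries were 336 and 449 TPM for microglia genes and 0.795 and 0.895 TPM for neuron genes. In addition, 5 microglia and 2 vessel genes are also in lists fixed for liver cells, and 9 microglia genes were among the 12 lowest genes. The YFP+ M library held the same genes at a low level. Among members with at least 20 TPM in both YFP− libraries, the YFP+ value was a median 6.96% of the YFP− value for 31 microglia genes (quartiles 5.65 and 13.7) and 4.98% for 15 brain vessel genes (4.76 and 6.11) between the M libraries. Between the FM libraries the medians were 0.602% and 1.17%. These are ratios of deposited values, not corrected for the shift of all genes. The median log2 difference of all tested genes was -1.01 between the M and -2.48 between the FM libraries, so the 2 pairs are not directly comparable.

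Most calls were lower in YFP+ libraries. Sequencing depth is argued against as the whole cause, since the FM pair had the larger median difference and a log2 depth ratio of 0.0026, against -0.93 in the M pair. A few dominant genes are argued against too: without the 158 genes in any library's top 100, and with the rest rescaled, at least 70.7% of the median difference was left in both pairs (-0.71 and -1.93). Transcript length (Spearman rho -0.34) and GC content (0.32) followed the change across genes, which are not independent replicates, yet the quartile of the 12144 genes with the shortest transcripts still had a median of -1.14, that with the highest GC content -1.25, and the 1121 genes in both -0.90, against -2.06 for the longest and for the lowest GC content. Open and untested are RNA amount or quality per library, since the YFP+ libraries differ from each other by a median of 1.05, and a difference between YFP+ and YFP− cells.

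The title start call of Hbb-b2 (log2 fold change 4.64) may come from reads shared with its near-identical neighbour Hbb-b1. The summed value of both genes had an FM minus M difference of -0.35. Hbb-b2 was low in the YFP− M library alone (0.770 TPM), where Hbb-b1 was at 1793 TPM, and between the YFP+ libraries it was higher in M (2173 against 1121 TPM), opposite to the call. A globin variant carried by the animals of that library was not tested.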
